A study of Danio rerio with 12 samples.

How the data were processed

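The counts were analysed as deposited, 1 file per library, and no read was aligned again here. Per the submitters' processing notes the 2x150 reads were trimmed with fastp, aligned with STAR to the danRer11 assembly, sorted with SAMtools and counted with featureCounts of the Subread package. Per the file headers the counts were made with featureCounts 2.0.0 and the GRCz11 annotation of release 107, as unstranded fragment counts of read pairs. Fragments that mapped to several places or overlapped several genes were not counted. A genome sequence was not used here, so duplicated sequence was not examined.

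Each file listed 32520 genes, of which 500 lay on no named chromosome and held no count. Of the rest 29201 were in the table of gene names. It gave 11971 of them a symbol in the human style, and 10959 of those were renamed through the order of 12 neighbouring genes on each side (at least 3 shared), 48 had a single candidate and 964 kept the symbol of the table. Tested on genes of known symbol, this rule named 1689 of 1725 and was right for 1686 (99.8%). A symbol given in this way can name the wrong paralog, and unstranded counts can hold fragments of an overlapping or antisense gene.

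Groups were taken from the sample labels, never from values. The replicate numbers in the labels were not treated as pairs. The main test was edgeR's quasi-likelihood F test with TMM scaling, filterByExpr by group (minimum count 10) and all 12 libraries in a single fit, with Benjamini-Hochberg adjustment per comparison and an adjusted p under 0.05. The interaction was the cell type difference of the head minus that of the trunk. Log2 fold changes are given with standard errors and CPM as mean and SD of 3 libraries. Genes named in the text were the reporter genes, the 6 per direction with the largest log2 fold change (at least 20 CPM in the higher group, groups fully apart, a symbol that is no clone name), up to 4 members per list with the smallest adjusted p, any member of the bone, cartilage, notochord and Hox lists, and the 5 transcription factor genes per direction with the smallest p. For the interaction they were the 6 per direction with the smallest p. Named outside that rule, because of their counts, were the top genes of libraries and the collagen paralogs. The result of 1 gene that met the rule is not reported here. A gene with no fragment in 1 group is given as a floor with 3 counts set in that group, and a gene with 1 to 3 fragments as a ratio with an exact 95% interval.

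The 25 gene lists covered bone matrix, cartilage matrix, the transcription factors of osteoblasts and of chondrocytes, Hox genes, cranial crest, BMP, Wnt, FGF, Hedgehog and retinoic acid genes, notochord, tendon, secretory pathway, proliferation, dissociation stress and marker genes of 9 other tissues. They were tested with limma's camera at a preset correlation of 0.01 and adjusted over 100 tests, of which 57 passed. With an estimated correlation 2 passed, and with fry 39. Member calls were also adjusted over each list alone. Some genes stood in several lists. The crest list shared dlx3b, dlx5a, dlx6a and msx1a with the osteoblast transcription factors, and barx1 with the chondrocyte transcription factors. Members with no matching symbol or too few counts were not tested. This left 6 of 13 erythrocyte genes and 11 of 20 leukocyte and osteoclast genes.

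The main test, the lists, the naming rule and these alternatives were fixed before the data were examined: RLE scaling, library totals only, no filter, a stricter filter of 5 CPM in 3 libraries, DESeq2's Wald test, only the 6 libraries compared, a block for the replicate number, a log2 fold change of at least 1, an adjusted p under 0.01, each library left out, an estimated correlation and fry. A further 2 alternatives were added after the data were seen, leaving out head osteoblast 1 and trunk chondrocyte 3 together and limma with sample quality weights.

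In a self test with known changes planted in 50 genes per size, the main test recovered 2%, 38%, 48% and 78% of log2 changes of 1, 2, 3 and 4 in head against trunk osteoblasts, with 2.4% false calls. Recovery of a log2 change of 2 was 28% in head osteoblasts against chondrocytes (5.7% false calls), 34% in the trunk (2.4%) and 34% in head against trunk chondrocytes (2.2%). A missed threshold is therefore no evidence of equality. The planted list was called in each comparison and 0, 1, 1 and 0 of 20 null lists were called, at an unadjusted camera p under 0.05. Genes were simulated independently of each other, so this self test cannot show how often lists of correlated genes are called wrongly. The estimated correlation of a real list reached 0.875, for skeletal muscle.

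Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.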

Results

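The series profiled RNA from skeletal cells sorted out of zebrafish at 15 days post fertilisation. The fish carried green fluorescent protein (GFP) driven through Gal4 from entpd5a, an ectonucleotidase gene of mineralising cells, and mCherry driven from an enhancer of col2a1a, the gene of the main cartilage collagen. Cells positive for GFP and negative for mCherry were taken as osteoblasts, and cells with the opposite pattern as chondrocytes. Each kind of cell was sorted from the head and from the trunk, which gave 4 groups of 3 libraries. The labels call the head osteoblasts classical and the trunk osteoblasts non-classical, and they place the trunk chondrocytes between the segments of the spine. The libraries of a group are labelled biological replicates, so p-values measure the spread between such samples. Counted fragments per library were 12498934, 7810245 and 8543067 in head osteoblasts and 9192297, 7815838 and 8822637 in trunk osteoblasts. They were 7640235, 14399220 and 14899564 in head chondrocytes and 8862993, 8218615 and 7438290 in trunk chondrocytes. Of 32520 annotated genes, 15147 passed the low count filter and were tested.

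Osteoblast and chondrocyte libraries separated on the first principal component, which held 32.8% of the variance. A pair of libraries stood apart from their groups. Head osteoblast 1 detected 14700 genes, against 16862 to 21292 in the other libraries, and 14348 when thinned to the depth of the shallowest library. It scored 184 on the second component (25.7% of the variance). Trunk chondrocyte 3 scored 136 on the third component (18%), and the skeletal muscle list held 10.85% of its counts, against at most 0.948% in any other library. The noncoding RNA malat1 was the top gene of every osteoblast library and took 8.2% of the counts of head osteoblast 1. It was also the top gene of head chondrocytes 2 and 3, at 5.4% and 4.53%. The cartilage matrix gene matn1 was the top gene of head chondrocyte 1 and of trunk chondrocytes 1 and 2, at 4.52%, 6.38% and 5.21%, and the muscle actin gene actc1b that of trunk chondrocyte 3, at 4.46%.

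**Figure D1:**
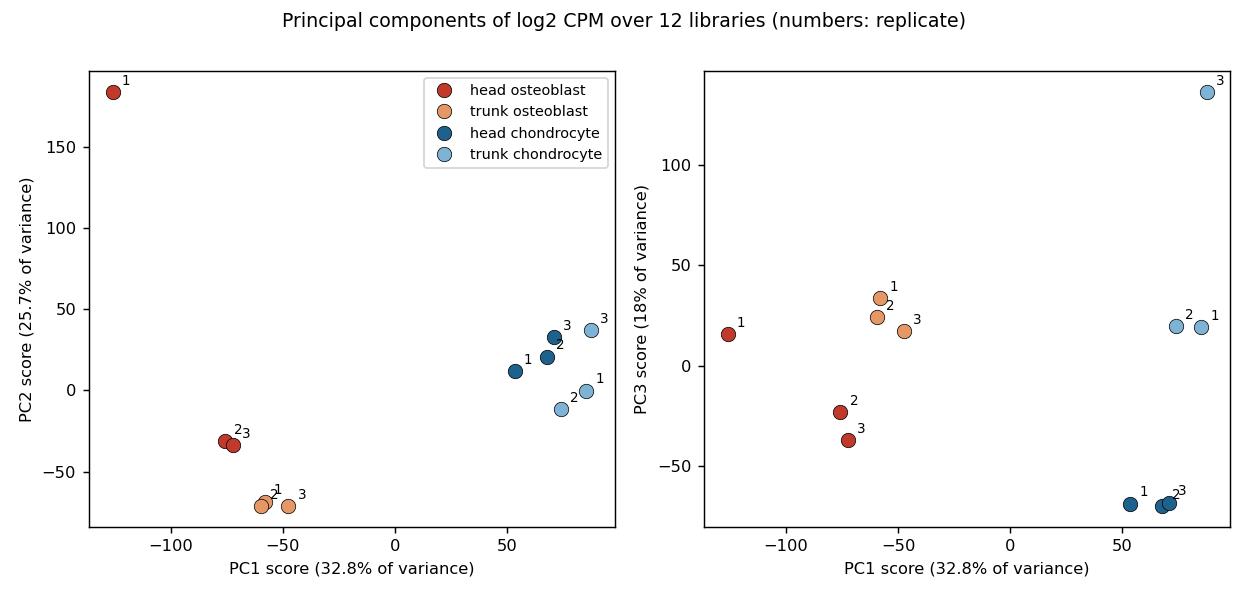
Scores of the 12 libraries on principal components 1 and 2 (left) and 1 and 3 (right) of log2 CPM (counts scaled to a library size of 1e6), with each axis labelled by its percentage of the variance and colours for the 4 groups. Head osteoblast 1 lies alone on component 2 (score 184) and trunk chondrocyte 3 on component 3 (score 136).

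The genes of the reporters were examined first. entpd5a (ENSDARG00000053481, chromosome 17, 45030407 to 45040813, GRCz11) reached 461 ± 223 CPM (mean ± SD, n = 3) in head osteoblasts and 575 ± 377 in trunk osteoblasts, against 46.2 ± 15.3 in head and 109 ± 86.7 in trunk chondrocytes. In the head its log2 fold change was 3.32 ± 0.79 (SE; adjusted p = 0.0138 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, as for each gene below), and every osteoblast library lay above every chondrocyte library. Without head chondrocyte 3 that adjusted p was 0.0707. In the trunk the log2 fold change was 2.40 ± 0.76 (adjusted p = 0.0471) with overlapping libraries. That call was lost, at an adjusted p of up to 0.147, without head osteoblast 2 or 3, trunk osteoblast 1 or 2, any head chondrocyte library, or trunk chondrocyte 1 or 3. Counts of col2a1a (ENSDARG00000069093, chromosome 8, 21195420 to 21219473) were low throughout, with 0 to 15 fragments in an osteoblast library and 11 to 121 in a chondrocyte library. It fell by 6.03 ± 1.1 on the log2 scale in trunk osteoblasts against trunk chondrocytes (adjusted p = 0.00303) and by 3.54 ± 0.93 in the head (adjusted p = 0.0221, up to 0.0792 without head osteoblast 2 or head chondrocyte 1 or 3). Its paralog col2a1b held 3636 to 98824 fragments per library. Likewise col1a1a held 22 fragments in all 12 libraries together, against 1631 to 64218 per library for col1a1b, so levels of col1a1a and col2a1a are not interpreted from these counts.

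The first comparison set head osteoblasts, labelled classical, against trunk osteoblasts, labelled non-classical. These labels coincide with the body part, so position and kind of osteoblast cannot be told apart here. Trunk osteoblasts expressed posterior Hox genes, which set position along the body axis, and dlx2a, dlx4a and hand2, transcription factor genes of the pharyngeal arches, were higher in head osteoblasts. hoxc13a (chromosome 23, 36052944 to 36055886) stood at 104 ± 28.4 CPM in the trunk and 0.196 ± 0.193 in the head (log2 fold change of head over trunk −9.08 ± 0.65, adjusted p = 2.71e-05). For hoxb13a (chromosome 3, 23654233 to 23655834), 148 ± 11.3 CPM in the trunk faced 1 fragment over the head group, a ratio of 5141 with an exact 95% interval of 922 to 203101. Such intervals, and the floors given below for genes with no fragment in a group, cover counting error only. dlx2a (chromosome 9, 3397407 to 3400729) was higher in the head, at 77.7 ± 24.6 against 4.24 ± 1.55 CPM (log2 4.19 ± 0.43, adjusted p = 0.000427), as was hand2, at 54.4 ± 16.6 against 1.39 ± 0.58 CPM (log2 5.28 ± 0.68, adjusted p = 0.00146). matn3b, which encodes the matrix protein matrilin 3, went the other way, at 3.19 ± 3.40 in the head and 331 ± 42.3 CPM in the trunk (log2 −6.66 ± 0.66, adjusted p = 0.000406). For each of these genes every library of the higher group lay above every library of the lower group.

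In this comparison 352 genes changed, 230 higher and 122 lower in the head, and 1877 had an unadjusted p under 0.05. Of 390 tested genes of transcription factor families, 34 rose and 41 fell. In the list of Hox paralog groups 4 to 13, 26 of 35 tested members were lower in the head and none was higher (29 lower and 1 higher adjusted over the list alone). The list test, limma's camera with a preset correlation, gave an adjusted p of 2.6e-31, and 0.0321 with an estimated correlation. This list, in both comparisons of head with trunk, was the only one called with an estimated correlation. hoxb10a had no fragment in the head and was at least 348-fold higher in the trunk, taking 3 counts over the head group as the floor. Of the cranial neural crest and pharyngeal arch list, 7 of 23 rose in the head (14 adjusted over the list alone; list adjusted p = 1.72e-10, adjusted p = 0.0682 with an estimated correlation). They included dlx4a (log2 4.55 ± 0.55, adjusted p = 0.000997) and barx1 (4.28 ± 0.56, adjusted p = 0.00166), a regulator of jaw cartilage. Outside the lists, the forebrain and eye transcription factor gene six3b (6.91 ± 0.72) and pou3f3a (4.18 ± 0.45) rose in the head. Photoreceptor, lens and neuronal markers rose in the same comparison, as given below. Whether the six3b and pou3f3a transcripts came from osteoblasts was not tested.

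None of the 26 tested bone matrix and mineralization genes passed the threshold, nor did any when adjusted over the list alone (list adjusted p = 0.831). The secreted phosphoprotein gene spp1 stood at 785 ± 140 CPM in the head and 854 ± 346 in the trunk (log2 −0.12 ± 0.51, adjusted p = 0.943), and sp7, encoding the osteoblast factor osterix, at 102 ± 12.9 and 121 ± 57.5 CPM (−0.25 ± 0.54, adjusted p = 0.879). Of 20 tested osteoblast transcription factors 1 rose and 1 fell (4 and 2 adjusted over the list alone; list adjusted p = 0.572). The riser was twist3, at 76.3 ± 17.1 against 10.3 ± 0.82 CPM (log2 2.89 ± 0.36, adjusted p = 0.00134). Among 11 chondrocyte transcription factors barx1 rose and nkx3-2, a joint and spine regulator, fell by 2.27 ± 0.38 to 61.3 ± 15.7 CPM in the head from 295 ± 32.1 in the trunk (adjusted p = 0.00669; 2 rose and 2 fell adjusted over the list alone, list adjusted p = 0.593). In the cartilage matrix list 3 of 24 rose and 1 fell (8 and 2 adjusted over the list alone; list adjusted p = 7.3e-05, adjusted p = 0.481 with an estimated correlation). The calls of the risers acana, otos and ucmab were lost without head osteoblast 3 or any trunk osteoblast library, and for ucmab also without any head chondrocyte library, with adjusted p up to 0.125, 0.106 and 0.175.

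Among 34 BMP signalling genes 3 rose and 4 fell (5 and 6 adjusted over the list alone; list adjusted p = 0.583). The BMP antagonist genes grem2b (log2 3.89 ± 0.55, adjusted p = 0.0027) and nog2 (2.46 ± 0.38, adjusted p = 0.00471) were higher in every head library. In the Wnt list 2 of 38 rose (5 rose and 1 fell adjusted over the list alone), in the Hedgehog list 2 of 16 rose (2 and 1), in the FGF list 1 of 19 fell (also 1), in the retinoic acid list 1 of 23 rose (also 1), and in the notochord list 3 of 14 rose and 2 fell (also 3 and 2). The tendon and fibroblast list had 1 of 14 lower in the head (also 1), the paraxial mesoderm factor gene tcf15 (log2 −6.19 ± 0.94, adjusted p = 0.004). Several of these calls were lost in other fits. gas1b of the Hedgehog list was lost without any single library except head osteoblast 1 (adjusted p up to 0.274), and fgfrl1a of the FGF list without any except head osteoblast 3 or trunk chondrocyte 3 (up to 0.137). aldh1a3 of the retinoic acid list was lost without head osteoblast 2 or 3, any trunk osteoblast or head chondrocyte library, or trunk chondrocyte 2 (up to 0.275). The Wnt calls, and the notochord calls other than nog2, were also lost in some settings. The lists in this paragraph did not pass the list test. The medians of the osteoblast transcription factor and Hedgehog lists lay below 0 and their means above it. The bone list had a median and mean below 0 and a list test that leaned up.

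Markers of other tissues moved with this comparison. Of the photoreceptor and lens list, 11 of 12 rose in the head (12 adjusted over the list alone; list adjusted p = 1.38e-13, adjusted p = 0.131 with an estimated correlation), and the list took 0.105%, 0.0487% and 0.0123% of the counts of the head osteoblast libraries against at most 0.000511% in trunk osteoblasts. The rod transducin gene gnat1 rose by 3.35 ± 0.50 (log2, adjusted p = 0.00382). Of 19 neuronal and glial genes 5 rose (14 rose and 1 fell adjusted over the list alone; list adjusted p = 2.36e-10, adjusted p = 0.136 with an estimated correlation), among them stmn1b (2.13 ± 0.34, adjusted p = 0.00515). In separate fits without head osteoblast 1, 2 or 3, 8, 3 and 4 of 19 neuronal genes were past the threshold. The epidermis, skeletal muscle, secretory pathway and proliferation lists had no member past the threshold under either adjustment and list adjusted p of 0.00838, 0.00672, 0.00948 and 0.0203 (adjusted p = 0.613, 0.656, 0.533 and 0.656 with an estimated correlation), up for epidermis and proliferation and down for the others. Of 12 liver, pancreas and gut genes 1 fell (2 adjusted over the list alone; list adjusted p = 0.791), with the median above 0 and the mean below. No dissociation stress, endothelial, erythrocyte, leukocyte or pigment gene passed (list adjusted p = 0.0597, 0.408, 0.13, 0.408 and 0.915), and adjusted over the list alone 1 endothelial and 1 pigment gene rose and 1 of each fell. The gene count fell to 170, 146 and 151 without trunk osteoblast 1, 2 or 3, and rose to 990 without head osteoblast 1 and trunk chondrocyte 3 together.

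**Figure D2:**
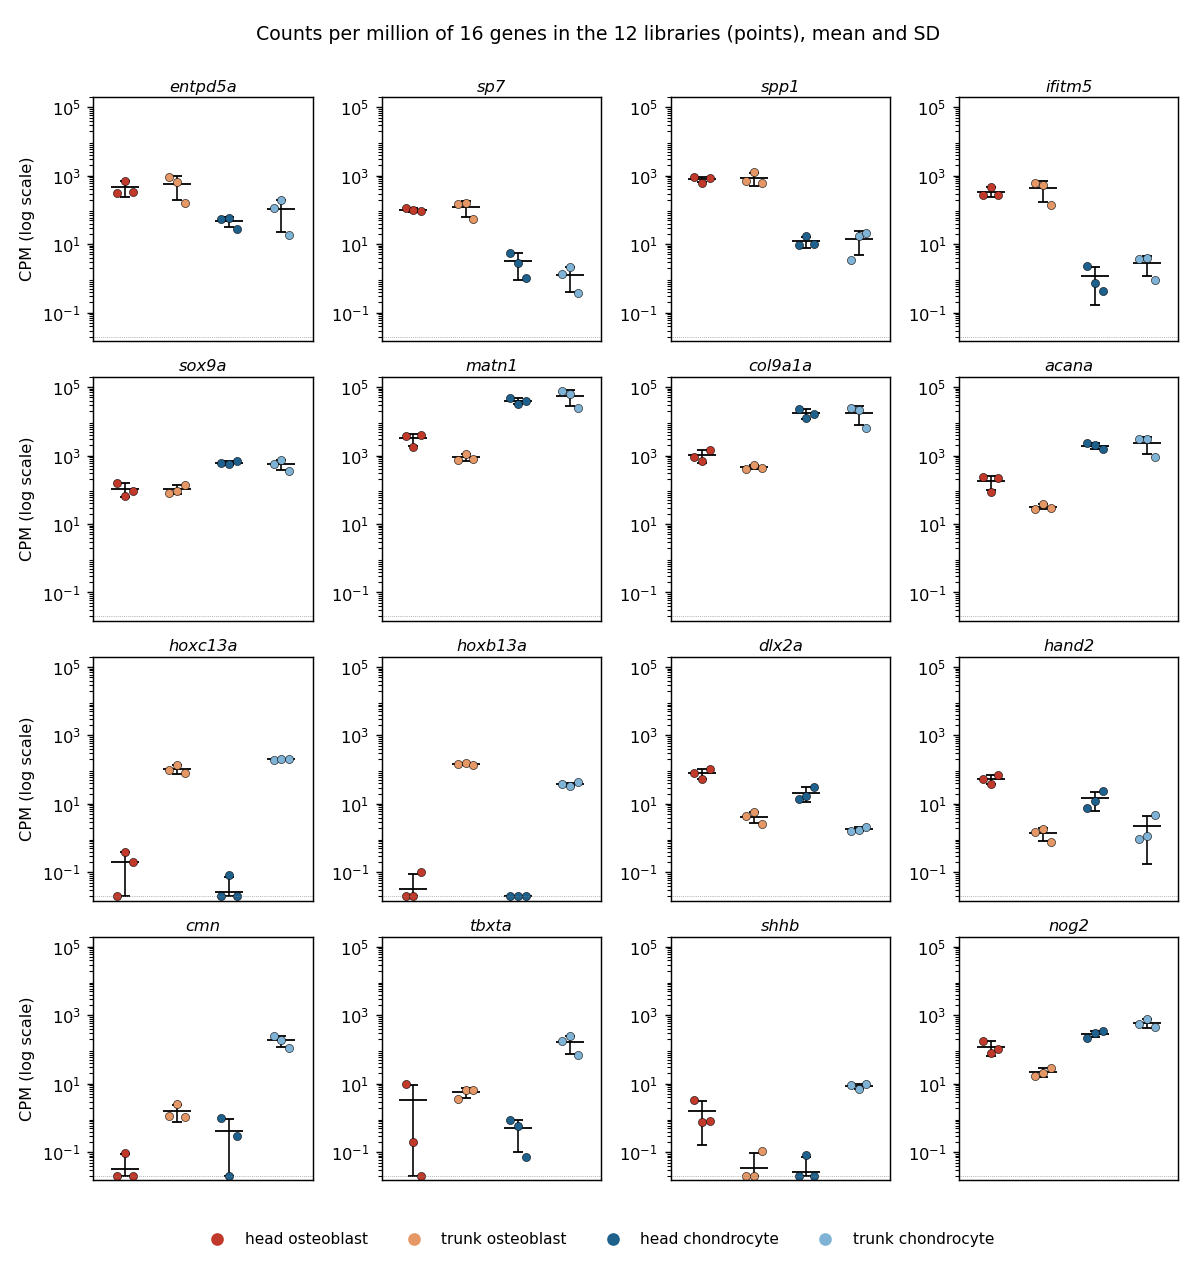
CPM of 16 marker genes in each of the 12 libraries on a log axis, with points for libraries, lines for the group mean and bars for the SD (n = 3 per group), and libraries with no fragment drawn on the dotted line at 0.02. hoxc13a averaged 104 CPM in trunk and 0.196 CPM in head osteoblasts, whereas sp7 averaged 121 and 102 CPM.

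The second comparison set head osteoblasts against the adjacent head chondrocytes, which served as controls. Many genes of the bone list were higher in the osteoblasts, and most of the cartilage list was higher in the chondrocytes, calls that the list test did not hold with an estimated correlation (adjusted p = 0.151 and 0.303). ifitm5 (chromosome 25, 7504314 to 7506547), which encodes a membrane protein of mineralising osteoblasts, stood at 344 ± 111 CPM in osteoblasts and 1.14 ± 0.974 in chondrocytes (log2 8.34 ± 0.86, adjusted p = 0.00013). spp1 stood at 785 ± 140 against 12.2 ± 4.39 CPM (6 ± 0.64, adjusted p = 0.00016), and phex, a phosphate-regulating peptidase gene, at 458 ± 58.5 against 4.59 ± 2.31 CPM (6.66 ± 0.56, adjusted p = 4.22e-05). In the chondrocytes matn1 (chromosome 19, 43314700 to 43338280) reached 39920 ± 8243 CPM against 3168 ± 1240 in osteoblasts (−3.66 ± 0.53, adjusted p = 0.000799), and acana, the gene of the cartilage proteoglycan aggrecan, 1960 ± 397 against 178 ± 80.4 CPM (−3.46 ± 0.51, adjusted p = 0.000861). Each of these genes separated all 3 osteoblast libraries from all 3 chondrocyte libraries.

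In all 2505 genes changed, 1398 higher and 1107 lower in osteoblasts, and 4661 had an unadjusted p under 0.05. The higher share was 55.8%, against 81.5% with library totals only, 65.4% with RLE scaling and 67% with DESeq2, which changes the test as well as the scaling. Library totals moved the median log2 fold change of all genes by 0.43 and RLE scaling by 0.15. Of 26 bone matrix genes 15 rose and none fell (16 adjusted over the list alone; list adjusted p = 1.73e-09, adjusted p = 0.151 with an estimated correlation). The largest fold among the list's genes with fragments in both groups was that of col10a1b (8.5 ± 1.06, adjusted p = 0.000317), and the mineral matrix gene scpp5 had no fragment in the chondrocytes and was at least 85.7-fold higher in osteoblasts. Of 20 osteoblast transcription factors 9 rose and none fell (10 rose and 1 fell adjusted over the list alone; list adjusted p = 8.05e-06, adjusted p = 0.119 with an estimated correlation). They included twist3 (5.77 ± 0.43, adjusted p = 2.12e-05), twist2 (3.85 ± 0.33, adjusted p = 5.02e-05), sp7 (5.07 ± 0.65, adjusted p = 0.000362) and runx2b (2.58 ± 0.54, adjusted p = 0.00705). Of 390 genes of transcription factor families 77 rose and 19 fell.

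Of 24 cartilage matrix genes 17 fell and 3 rose in head osteoblasts (17 and 4 adjusted over the list alone; list adjusted p = 7.45e-08, adjusted p = 0.303 with an estimated correlation). epyc (−4.60 ± 0.51, adjusted p = 0.000174) and col9a1a (−4.07 ± 0.55, adjusted p = 0.000475) were among those that fell. The 3 that rose were hapln1a, which encodes a hyaluronan link protein (4.79 ± 0.66, adjusted p = 0.000582), col11a1b (2.04 ± 0.56, adjusted p = 0.0277) and ucmaa (1.47 ± 0.45, adjusted p = 0.0435). The col11a1b call was lost without head osteoblast 2 or 3 or head chondrocyte 2 or 3 (adjusted p up to 0.115), and that of ucmaa without those or trunk osteoblast 1 or 2 or trunk chondrocyte 1 (up to 0.145). Among 11 chondrocyte transcription factors 5 fell and 2 rose (the same numbers adjusted over the list alone; list adjusted p = 0.411). The cartilage master regulator gene sox9a stood at 106.6 ± 46.4 CPM in osteoblasts and 613 ± 65.5 in chondrocytes (−2.52 ± 0.38, adjusted p = 0.00103), and its partners sox5 and sox6 fell by 2.11 ± 0.37 and 2.15 ± 0.33. Its paralog sox9b was among the risers (3.40 ± 0.77, adjusted p = 0.0108, 0.0547 without head chondrocyte 2).

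Signalling and matrix lists followed. Of 38 Wnt genes 17 rose and 5 fell (22 and 5 adjusted over the list alone; list adjusted p = 0.000263, adjusted p = 0.303 with an estimated correlation). The secreted Wnt inhibitor genes dkk3b (5.56 ± 0.38, adjusted p = 2.12e-05) and wif1 (3.54 ± 0.41, adjusted p = 0.000226) rose, whereas frzb, another of them, stood at 237 ± 42.0 CPM in osteoblasts and 1416 ± 413 in chondrocytes (−2.58 ± 0.31, adjusted p = 0.000239). Of 34 BMP genes 11 rose and 2 fell (13 and 2 adjusted over the list alone; list adjusted p = 0.00038, adjusted p = 0.3 with an estimated correlation). Among them bmp8a rose by 5.25 ± 0.48 (adjusted p = 6.78e-05), and the antagonist gene grem1b had a ratio of 263 over 3 fragments in the chondrocytes (exact 95% interval 89.8 to 1280). Of 14 tendon and fibroblast genes 9 rose (9 rose and 1 fell adjusted over the list alone; list adjusted p = 1.28e-06, adjusted p = 0.151 with an estimated correlation). They included tnmd (4.28 ± 0.60, adjusted p = 0.000597) and thbs4b (4.22 ± 0.49, adjusted p = 0.000223). The crest and arch list had 9 of 23 higher in osteoblasts (also 9 adjusted over the list alone; list adjusted p = 1.08e-06, adjusted p = 0.119 with an estimated correlation), and the retinoic acid list 6 of 23 (also 6; 0.00214, adjusted p = 0.151 with an estimated correlation), with crabp2a at 3.99 ± 0.44 (adjusted p = 0.000181). Of 26 secretory pathway genes 11 fell and none rose (14 fell adjusted over the list alone; list adjusted p = 2.23e-05, adjusted p = 0.28 with an estimated correlation). sec24d, a coat gene of vesicles that carry procollagen, fell by 2.46 ± 0.34 to 52.3 ± 19.3 CPM from 287 ± 32.7 (adjusted p = 0.000606). The calls of 2 of its members, canx and selenos, were lost with library totals only.

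The FGF list had 5 risers and 2 fallers among 19 genes (6 and 2 adjusted over the list alone; list adjusted p = 0.123), the Hedgehog list 5 and 2 among 16 (also 5 and 2; 0.0311, adjusted p = 0.538 with an estimated correlation), the notochord list 4 and 2 among 14 (also 4 and 2; 0.306), and the Hox list 3 and 0 among 35 (2 and 0; 0.489). The decoy receptor gene fgfrl1a rose by 2.22 ± 0.34 (adjusted p = 0.000994). Members of several marker lists of other cell types were higher in head osteoblasts. Neuronal and glial genes rose in 14 of 19 cases (18 adjusted over the list alone; list adjusted p = 2.36e-09, adjusted p = 0.136 with an estimated correlation) and photoreceptor and lens genes in 7 of 12 (12; 7.47e-07, adjusted p = 0.236 with an estimated correlation). Epidermal genes rose in 4 of 14 cases (12; 2.45e-05, adjusted p = 0.371 with an estimated correlation), with the keratin gene krt4 at 3.26 ± 0.53 (adjusted p = 0.00156). Of 12 endothelial genes 5 rose and 1 fell (also 5 and 1; 0.0128, adjusted p = 0.136 with an estimated correlation), and of 11 leukocyte and osteoclast genes 4 rose (5; 0.00327, adjusted p = 0.119 with an estimated correlation), with the collagen-degrading cathepsin gene ctsk at 3.90 ± 0.41 (adjusted p = 0.000149).

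Skeletal muscle had 1 riser of 17 (13 adjusted over the list alone; list adjusted p = 0.000489, adjusted p = 0.606 with an estimated correlation), liver, pancreas and gut 1 of 12 (7; 0.0177, 0.558 as adjusted p with an estimated correlation), pigment cells 1 of 6 (2; 0.0141, 0.272 likewise) and erythrocytes 0 of 6 (0; 0.0136, 0.426 likewise). Dissociation stress genes rose in 4 of 30 cases (also 4; list adjusted p = 0.0743) and proliferation genes in 1 of 26 (0 adjusted over the list alone; 0.411). The kinase gene ltk of the pigment list rose by 3.11 ± 0.50 (adjusted p = 0.00151). The gene count fell to 1661 without head osteoblast 2 and to 1614, 1352 and 1220 without head chondrocyte 1, 2 or 3. It rose to 5311 without head osteoblast 1 and trunk chondrocyte 3 together.

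The third comparison set trunk osteoblasts against the chondrocytes of the spine. Here too many genes of the bone list were higher in the osteoblasts, and most of the cartilage list and several notochord genes were higher in the chondrocytes. The list test did not hold these calls with an estimated correlation (adjusted p = 0.303, 0.151 and 0.254). ifitm5 stood at 437 ± 262 CPM in osteoblasts and 2.86 ± 1.70 in chondrocytes (log2 7.23 ± 0.81, adjusted p = 0.000118), and enam, a gene of the mineral matrix protein family, at 2322 ± 1169 against 13.3 ± 10.9 CPM (7.44 ± 1.27, adjusted p = 0.00199). matn1 reached 54660 ± 27370 CPM in chondrocytes and 887 ± 188 in osteoblasts (−5.94 ± 0.60, adjusted p = 6.96e-05), and smoc2, a matrix gene, 240 ± 79.4 against 1.85 ± 0.296 CPM (−7.02 ± 0.49, adjusted p = 2.52e-05). The notochord gene cmn (calymmin, chromosome 12, 13118540 to 13164249) stood at 184 ± 68.5 CPM in chondrocytes and 1.59 ± 0.826 in osteoblasts (−6.85 ± 0.74, adjusted p = 0.000102). In each of these genes all 3 libraries of the higher group exceeded all 3 of the lower group.

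In this comparison 2593 genes changed, 1194 higher and 1399 lower in osteoblasts, and 4835 had an unadjusted p under 0.05. With library totals only, which moved the median log2 fold change of all genes by 0.51, the higher share was 79.9% and not 46%. Of 26 bone matrix genes 14 rose and none fell (15 rose and 3 fell adjusted over the list alone; list adjusted p = 2.43e-05, adjusted p = 0.303 with an estimated correlation). They included spp1 (5.93 ± 0.64, adjusted p = 0.000102), phex (6.02 ± 0.55, adjusted p = 4.11e-05) and the phosphatase gene alpl (2.49 ± 0.40, adjusted p = 0.00131). Of 20 osteoblast transcription factors 9 rose and none fell, also when adjusted over the list alone (list adjusted p = 3.44e-05, adjusted p = 0.119 with an estimated correlation). sp7 rose by 6.53 ± 0.72 (adjusted p = 0.000107) and twist2 by 4.48 ± 0.34 (adjusted p = 2.86e-05), whereas runx2b stood at 44.2 ± 15.3 CPM in osteoblasts and 51.6 ± 25.8 in chondrocytes (−0.22 ± 0.51, adjusted p = 0.808). Of 24 cartilage matrix genes 20 fell and 3 rose, also when adjusted over the list alone (list adjusted p = 7.32e-16, adjusted p = 0.151 with an estimated correlation). acana fell by 6.19 ± 0.58 (adjusted p = 5.13e-05), and the 3 that rose were col11a1b (3 ± 0.58, adjusted p = 0.00446), hapln1a (2.76 ± 0.60, adjusted p = 0.00839) and matn3b (2.45 ± 0.54, adjusted p = 0.00869).

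Among 11 chondrocyte transcription factors 2 fell and 2 rose (3 and 3 adjusted over the list alone; list adjusted p = 0.894), and the list's median lay above 0 and its mean below. sox9a fell by 2.42 ± 0.38 (adjusted p = 0.0012) and sox6 by 2.3 ± 0.33 (adjusted p = 0.000694). Of 14 notochord genes 6 fell and 2 rose in osteoblasts, also when adjusted over the list alone (list adjusted p = 0.00737, adjusted p = 0.254 with an estimated correlation). The brachyury gene tbxtb stood at 13.5 ± 6.68 CPM in chondrocytes and 0.319 ± 0.223 in osteoblasts (−5.38 ± 0.89, adjusted p = 0.00155). For the signal gene shhb 1 fragment in the osteoblasts faced 8.46 ± 1.45 CPM in the chondrocytes (ratio 248, exact 95% interval 43.9 to 9852). nog2, held in the notochord and BMP lists, stood at 597 ± 173 CPM in chondrocytes and 22.0 ± 5.93 in osteoblasts (−4.76 ± 0.42, adjusted p = 3.5e-05). One member, ntd5, rose by 2.90 ± 0.38 (adjusted p = 0.000368). The Hox list had 5 of 35 higher in osteoblasts (also 5 adjusted over the list alone; list adjusted p = 5.36e-09, adjusted p = 0.136 with an estimated correlation), with hoxb13a at 148 ± 11.3 against 37.6 ± 4.37 CPM (1.98 ± 0.32, adjusted p = 0.0023). The calls of the other 4, hoxa11a, hoxc11a, hoxd11a and hoxd12a, were lost without any of the trunk osteoblast libraries in turn (adjusted p up to 0.0777, 0.0816, 0.11 and 0.081). They were also lost without trunk chondrocyte 1 (hoxc11a), 2 (hoxa11a) or either (hoxd11a, hoxd12a).

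Of 34 BMP genes 12 rose and 3 fell (14 and 3 adjusted over the list alone; list adjusted p = 0.00171, adjusted p = 0.336 with an estimated correlation). The antagonist gene chrd rose by 4.64 ± 0.49 (adjusted p = 9.1e-05) and gdf10a by 4.21 ± 0.46 (adjusted p = 0.000104). Of 38 Wnt genes 18 rose and 5 fell (21 and 6 adjusted over the list alone; list adjusted p = 0.000232, adjusted p = 0.303 with an estimated correlation). The co-receptor gene lrp5 rose by 1.99 ± 0.26 (adjusted p = 0.000351) and the receptor gene lgr4 fell by 2.62 ± 0.34 (adjusted p = 0.000378). The Hedgehog list had 5 risers and 3 fallers of 16 (7 and 3 adjusted over the list alone; list adjusted p = 0.128). The pathway inhibitor gene hhip rose by 4.80 ± 0.41 (adjusted p = 3.23e-05) and the ligand gene ihha fell by 3.16 ± 0.47 (adjusted p = 0.000862). The FGF list had 4 risers and 2 fallers of 19 (4 and 3 adjusted over the list alone; list adjusted p = 0.238), with fgfr3 at −3 ± 0.4 (adjusted p = 0.000406). Of 14 tendon and fibroblast genes 11 rose and 1 fell (12 and 1 adjusted over the list alone; list adjusted p = 6.73e-08, adjusted p = 0.14 with an estimated correlation). The keratan sulfate proteoglycan gene lum rose by 4.13 ± 0.55 (adjusted p = 0.000412). Of 26 secretory pathway genes 9 fell and none rose (11 fell and 1 rose adjusted over the list alone; list adjusted p = 0.00064, adjusted p = 0.371 with an estimated correlation). The disulfide isomerase gene p4hb fell by 2.68 ± 0.55 (adjusted p = 0.00563). The calls of pdia6 and sec23a were lost with library totals only. Of 390 genes of transcription factor families 83 rose and 12 fell. foxp4 stood at 1277 ± 289 against 151 ± 5.59 CPM (3.08 ± 0.32, adjusted p = 8.39e-05) and foxa3 fell by 5.66 ± 0.68 (adjusted p = 0.000205).

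The crest and arch list had 7 of 23 higher in trunk osteoblasts (9 adjusted over the list alone; list adjusted p = 0.00319, adjusted p = 0.254 with an estimated correlation) and the retinoic acid list 4 of 23 (also 4; 0.00302, adjusted p = 0.151 with an estimated correlation). The crest risers included dlx3b and dlx5a, which also counted among the risers of the osteoblast transcription factor list. Among markers of other cell types, 4 of 19 neuronal genes rose (also 4; 0.0177, adjusted p = 0.54 with an estimated correlation), 4 of 12 endothelial genes rose and 1 fell (also 4 and 1; 0.0616), and of 11 leukocyte and osteoclast genes ctsk rose (3.25 ± 0.39, adjusted p = 0.000218; also 1 adjusted over the list alone; 0.0125, adjusted p = 0.136 with an estimated correlation). The muscle list, high in trunk chondrocyte 3, had 1 of 17 lower in osteoblasts (10 adjusted over the list alone; list adjusted p = 0.00772, adjusted p = 0.656 with an estimated correlation), and without that library its list test turned up at an adjusted p of 0.979. That member, ckmb, was not past the threshold in 15 of 20 other settings (adjusted p up to 0.825). Of the neuronal risers, elavl3 was not past the threshold in 8 of 21 other settings. No photoreceptor, erythrocyte or proliferation gene changed under either adjustment. Of the other lists, 1 of 14 epidermal genes fell (0 adjusted over the list alone; list adjusted p = 0.411), 1 of 12 liver, pancreas and gut genes fell (5; 0.137), 1 of 6 pigment genes rose (also 1; 0.102) and 2 of 30 dissociation stress genes rose (also 2; 0.026, adjusted p = 0.741 with an estimated correlation). The gene count rose to 4379 without head osteoblast 1 and to 4334 without head osteoblast 1 and trunk chondrocyte 3 together. Without trunk chondrocyte 3 alone it was 2139, and 1876 of these genes were among the 2593 of the main test. The count fell to 1565, 1297 and 1517 without trunk osteoblast 1, 2 or 3 and to 1719 without trunk chondrocyte 1.

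**Figure D3:**
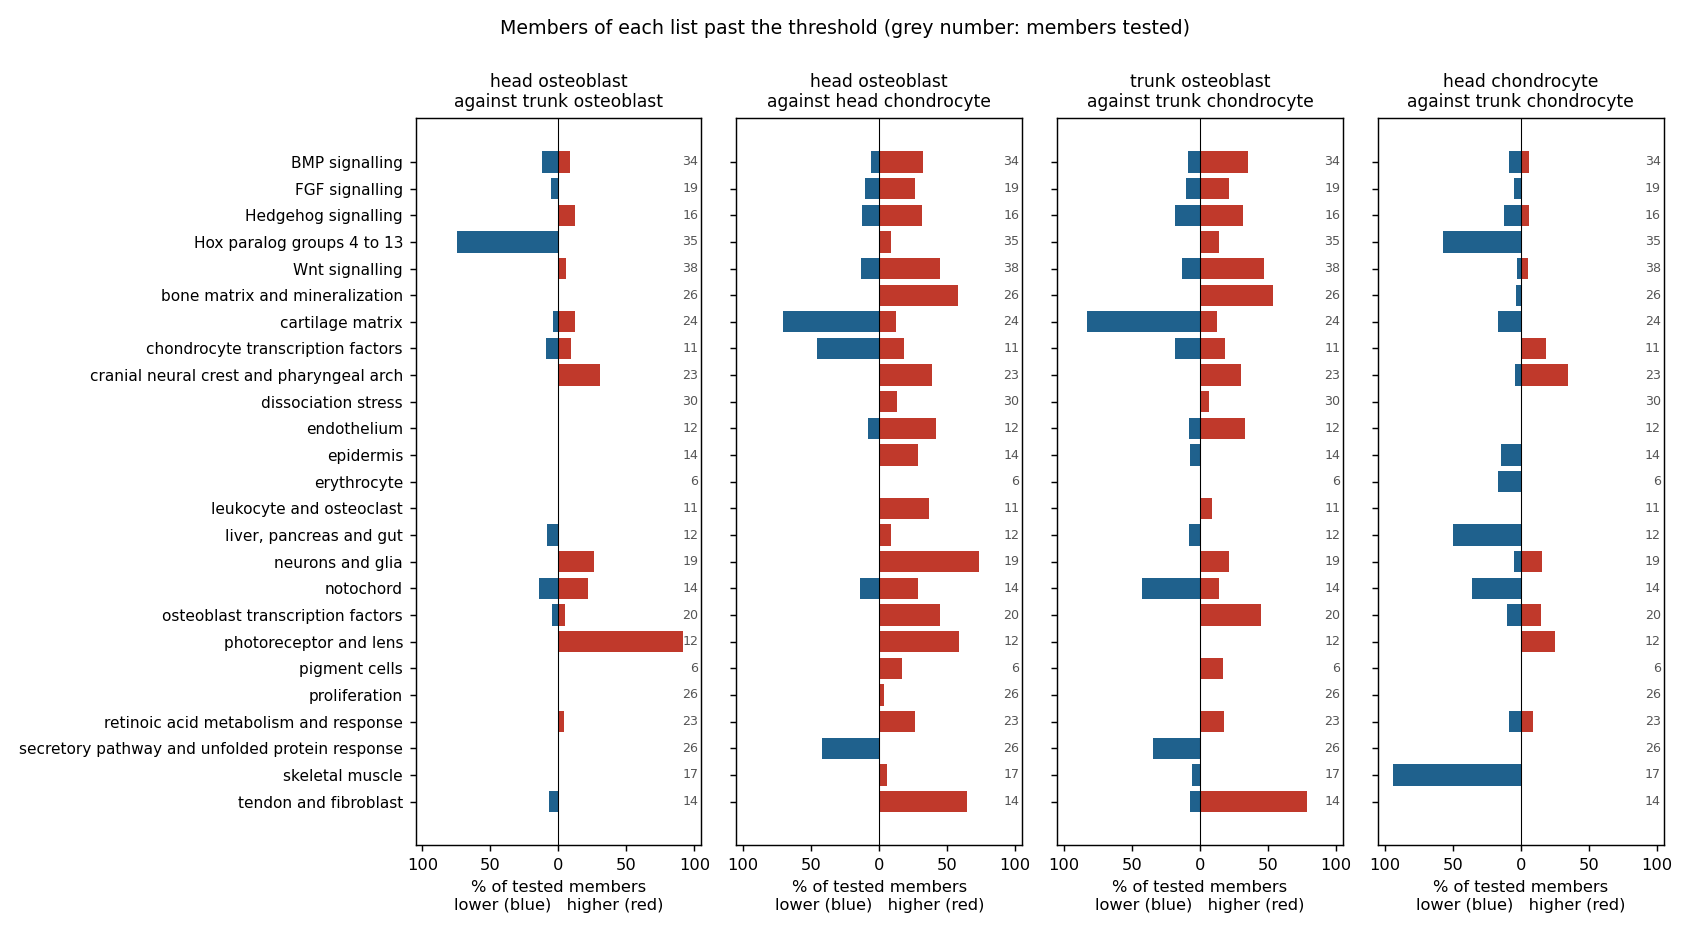
Percentage of the tested members of the 25 gene lists that were higher (red, to the right) or lower (blue, to the left) in the first group of each of the 4 comparisons at an adjusted p under 0.05, with the number of tested members in grey. In the Hox list 26 of 35 members were lower in head than in trunk osteoblasts and 20 of 35 in head than in trunk chondrocytes.

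The fourth comparison set head against trunk chondrocytes and so gave the position-dependent differences of the control cells. Many Hox genes were again higher in the trunk, dlx2a, dlx4a and dlx5a were higher in the head, and several genes of the notochord, the embryonic axial rod, were higher in the trunk cells. Whether the notochord transcripts of the trunk sorts came from chondrocytes or from notochord cells sorted with them was not tested. For hoxc13a 201 ± 5.37 CPM in the trunk faced 1 fragment over the head group (ratio 6649, exact 95% interval 1193 to 262686), and hoxb13a had no fragment in the head and was at least 413-fold higher in the trunk. dlx2a stood at 21.1 ± 9.45 CPM in the head and 1.86 ± 0.285 in the trunk (log2 3.51 ± 0.44, adjusted p = 0.00136). cmn stood at 184 ± 68.5 CPM in the trunk and 0.424 ± 0.506 in the head (−8.96 ± 0.84, adjusted p = 0.000317). matn3a, encoding the cartilage protein matrilin 3, stood at 329 ± 9.18 against 9.28 ± 9.25 CPM (−5.14 ± 0.63, adjusted p = 0.0013), and in each of these genes all 3 libraries of the higher group exceeded all 3 of the lower group.

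In this comparison 517 genes changed, 157 higher and 360 lower in the head, and 2453 had an unadjusted p under 0.05. With library totals only, which moved the median log2 fold change of all genes by 0.17, the higher share was 43.6% and not 30.4%. Of 35 Hox genes 20 fell and none rose (30 fell and 1 rose adjusted over the list alone; list adjusted p = 2.2e-31, adjusted p = 0.0321 with an estimated correlation). Of 23 crest and arch genes 8 rose and 1 fell (14 and 2 adjusted over the list alone; list adjusted p = 1.02e-07, adjusted p = 0.119 with an estimated correlation). barx1 rose by 4.93 ± 0.65 (adjusted p = 0.00191) and dlx5a by 3.48 ± 0.48 (adjusted p = 0.00237). Outside the lists the craniofacial factor gene six2a rose by 2.93 ± 0.31 (adjusted p = 0.000542), and of 390 genes of transcription factor families 32 rose and 33 fell. Of 14 notochord genes 5 fell and none rose (7 fell and 3 rose adjusted over the list alone; list adjusted p = 0.00015, adjusted p = 0.136 with an estimated correlation). Besides cmn they were tbxtb (1 fragment in the head, ratio 468, exact 95% interval 83.4 to 18567), shhb (1 fragment, ratio 279, interval 49.4 to 11086), foxa2 (−5.52 ± 0.93, adjusted p = 0.00899, 0.0658 without head chondrocyte 3) and tbxta (−8.47 ± 1.51, adjusted p = 0.012, up to 0.0769 without any of the head chondrocyte libraries in turn).

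Of 24 cartilage matrix genes 4 fell and none rose (5 fell adjusted over the list alone; list adjusted p = 0.0114, adjusted p = 0.656 with an estimated correlation). Besides matn3a they were matn3b (−5.56 ± 0.65, adjusted p = 0.000913), col9a1b (−5.25 ± 0.65, adjusted p = 0.0013) and susd5 (−4.71 ± 0.94, adjusted p = 0.0189, up to 0.112 without any of the head chondrocyte libraries in turn). matn1 (−0.45 ± 0.48, adjusted p = 0.748), acana (−0.25 ± 0.46, adjusted p = 0.878) and sox9a (0.15 ± 0.36, adjusted p = 0.916) did not pass the threshold. Of 11 chondrocyte transcription factors 2 rose, also when adjusted over the list alone, barx1 and prrx1b (2.38 ± 0.38, adjusted p = 0.00666; list adjusted p = 0.0402, adjusted p = 0.371 with an estimated correlation). Of 26 bone matrix genes 1 fell (5 fell and 1 rose adjusted over the list alone; list adjusted p = 0.000771, adjusted p = 0.429 with an estimated correlation), and of 20 osteoblast transcription factors 3 rose and 2 fell (5 and 4; 0.723). Among 34 BMP genes 2 rose and 3 fell (2 and 7; 0.0256, adjusted p = 0.533 with an estimated correlation), with bmp7b at −2.49 ± 0.36 (adjusted p = 0.00349). Among 38 Wnt genes 2 rose and 1 fell (7 and 1; 0.123), with frzb at 1.87 ± 0.30 (adjusted p = 0.00692). Among 19 FGF genes fgfr4 fell by 3.33 ± 0.45 (adjusted p = 0.0022; also 1 adjusted over the list alone; 0.047, adjusted p = 0.606 with an estimated correlation). Among 16 Hedgehog genes 1 rose and 2 fell (2 and 3; 0.572), with the median above 0 and the mean below. The riser boc was lost without any single library except head osteoblast 1 or trunk chondrocyte 2 (adjusted p up to 0.209), and ihha without trunk osteoblast 1, any head chondrocyte library, or trunk chondrocyte 1 or 2 (up to 0.134). Among 23 retinoic acid genes 2 rose and 2 fell (3 and 3; 0.894). The binding protein genes crabp2a (−4.35 ± 0.45, adjusted p = 0.000511) and rbp5 (−2.17 ± 0.25, adjusted p = 0.00083) were the fallers. The calls of both risers of that list, and all but 1 of the osteoblast transcription factor calls, were lost in some settings. No tendon, secretory pathway, proliferation or dissociation stress gene changed under either adjustment, although the stress list test leaned down at an adjusted p of 0.0393 (adjusted p = 0.76 with an estimated correlation).

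Of 17 skeletal muscle genes 16 were lower in head than in trunk chondrocytes (17 adjusted over the list alone; list adjusted p = 3.14e-20, adjusted p = 0.151 with an estimated correlation). myhz2, a fast myosin gene, stood at 297 ± 350 CPM in the trunk and 5.35 ± 2.59 in the head (−5.80 ± 0.96, adjusted p = 0.00856). Its trunk libraries held 57.5, 134 and 699 CPM, the highest in trunk chondrocyte 3. Of 12 liver, pancreas and gut genes 6 fell (8 adjusted over the list alone; list adjusted p = 8.05e-06, adjusted p = 0.254 with an estimated correlation). They included pck1, a gluconeogenesis gene (−3.87 ± 0.50, adjusted p = 0.00161), and the list took 0.362% of the counts of trunk chondrocyte 3, against 0.019% and 0.0313% in trunk chondrocytes 1 and 2. The digestive enzyme gene amy2a had no fragment in the head and averaged 100 ± 172 CPM in the trunk, a mean carried by trunk chondrocyte 3 (1.35, 1.04 and 298.6 CPM in the trunk libraries; adjusted p = 0.0402, up to 0.148 without head osteoblast 2 or 3, or any trunk osteoblast or head chondrocyte library). In separate fits without trunk chondrocyte 1, 2 or 3, 6, 6 and 3 of 12 genes of the list were past the threshold. Of 14 epidermal genes 2 fell (12 adjusted over the list alone; 6.74e-07, adjusted p = 0.303 with an estimated correlation). Of 12 photoreceptor and lens genes 3 rose (6; 0.000457, adjusted p = 0.371 with an estimated correlation). Among them sagb, an arrestin gene, rose by 3.47 ± 0.6 (adjusted p = 0.0105). Of 19 neuronal genes 3 rose and 1 fell (4 and 1; 0.102). No endothelial, leukocyte or pigment gene changed, except 4 leukocyte genes lower when adjusted over the list alone (list adjusted p = 0.0166, adjusted p = 0.14 with an estimated correlation). In the erythrocyte list tmod4, an actin-capping tropomodulin gene, fell (−6.49 ± 1.26, adjusted p = 0.0165, up to 0.101 without any head chondrocyte library; also 1 adjusted over the list alone, list adjusted p = 0.5). The gene count rose to 1221 without head osteoblast 1 and to 1440 without that library and trunk chondrocyte 3 together. Without trunk chondrocyte 3 alone it was 397, and 308 of these genes were among the 517 of the main test. The count fell to 327 and 334 without trunk osteoblast 1 or 2 and to 147, 131 and 119 without head chondrocyte 1, 2 or 3.

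The cell type differences of the head and of the trunk share no library and were compared across genes, which are not independent replicates. Over 15147 genes the log2 fold changes of osteoblasts over chondrocytes correlated at r = 0.499 (Spearman correlation 0.515), and 70.6% had the same sign. In both body parts 657 genes were higher in osteoblasts (110 expected of independent lists) and 689 were lower (102 expected). Both sets of calls came from the same fit, with a shared estimate of each gene's spread. Without head osteoblast 1, which is not part of the trunk comparison, the trunk count went from 2593 to 4379. The lists are therefore not independent, and the expected numbers are a reference only. A further 20 genes were past both thresholds in opposite directions. Bone genes such as ifitm5, spp1, phex and sp7 were among the shared higher genes, and matn1, acana, col9a1a and sox9a among the shared lower ones.

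**Figure D4:**
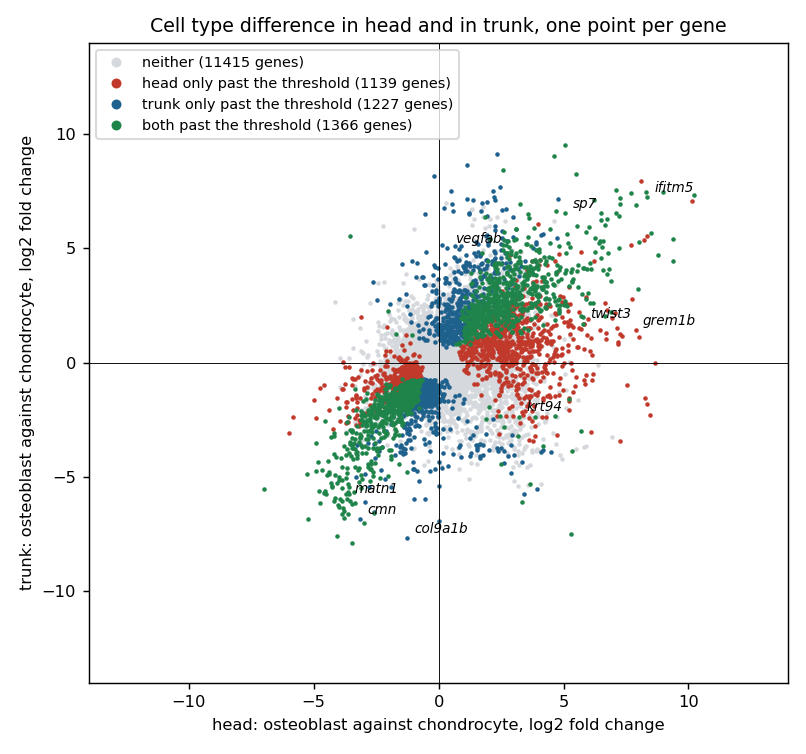
Log2 fold change of osteoblasts over chondrocytes in the head (horizontal) and in the trunk (vertical), with 1 point per tested gene coloured by where its adjusted p was under 0.05. In both body parts 1366 genes passed, in the head alone 1139, in the trunk alone 1227 and in neither 11415.

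The difference between the head and trunk cell type effects was tested as an interaction. The cell type difference was unequal in 74 genes, more positive in the head for 52 and in the trunk for 22, and 1704 had an unadjusted p under 0.05. The keratin gene krt94 was higher in head osteoblasts than in head chondrocytes, at 99.98 ± 15.8 against 10.7 ± 1.70 CPM, and lower in trunk osteoblasts than in trunk chondrocytes, at 13.1 ± 0.622 against 67.7 ± 8.30 CPM (interaction 5.59 ± 0.35, adjusted p = 1.76e-05). The angiogenic factor gene vegfab stood at 77.8 ± 2.88 CPM in trunk osteoblasts and 2.44 to 4.56 CPM in the other groups (−4.66 ± 0.55, adjusted p = 0.00474), and alpi.1, an alkaline phosphatase gene of the intestinal type, at 369 ± 90.0 CPM in trunk osteoblasts and 10.3 to 15.0 CPM elsewhere (−5.01 ± 0.56, adjusted p = 0.00474). col9a1b stood at 241 ± 94.8 CPM in trunk chondrocytes and 1.17 to 6.40 CPM in the other groups (6.43 ± 0.89, adjusted p = 0.0092). The count rose to 158 without head osteoblast 1, 113 without trunk chondrocyte 3 and 358 without both. It was 28 without head osteoblast 2, 23, 21 and 22 without trunk osteoblast 1, 2 or 3, 48, 30 and 24 without head chondrocyte 1, 2 or 3, and 46 without trunk chondrocyte 2.

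**Figure D5:**
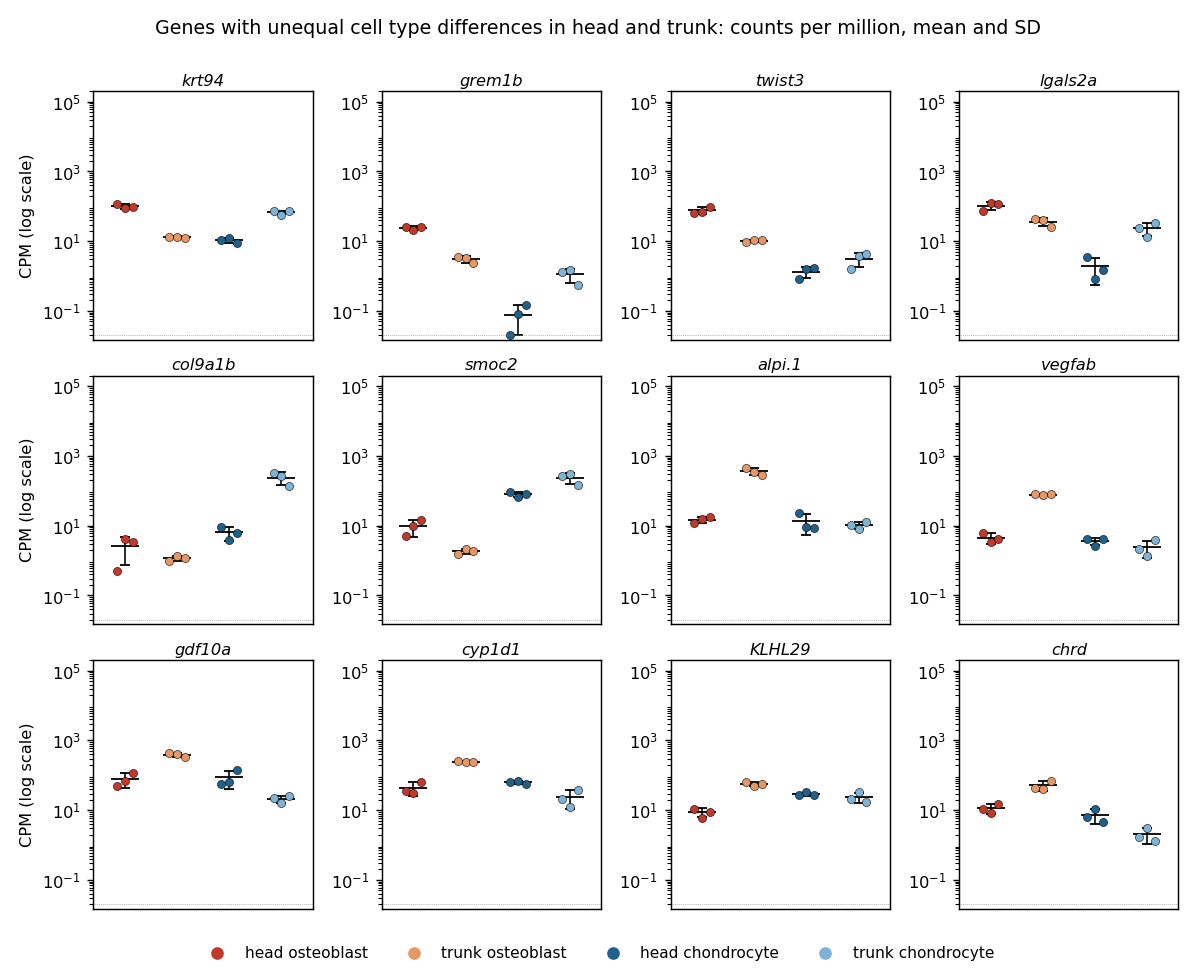
CPM of 12 genes with unequal cell type differences in head and trunk, for each of the 12 libraries on a log axis, with points for libraries, lines for the group mean and bars for the SD (n = 3 per group), and libraries with no fragment drawn on the dotted line at 0.02. krt94 averaged 99.98 CPM in head and 13.1 CPM in trunk osteoblasts, against 10.7 and 67.7 CPM in the chondrocytes.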

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

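The test of reads lost over stretches and the test of eye RNA were chosen after the result was seen, and the other tests of this part were chosen before.

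The cell type difference was unequal in head and trunk for 74 genes. The head minus trunk log2 differences were 5.59 for krt94, 6.46 for grem1b, 4.07 for twist3, 5.19 for lgals2a, 6.43 for col9a1b and 4.01 for smoc2. They were −5.01 for alpi.1, −4.66 for vegfab, −4.34 for gdf10a, −3.92 for cyp1d1, −2.95 for KLHL29 (ENSDARG00000087688) and −4.03 for chrd. For grem1b head chondrocytes averaged 0.0754 ± 0.0724 CPM and trunk chondrocytes 1.13 ± 0.51, so the size of its difference rests on few fragments. The call of smoc2 was lost without trunk osteoblast 1 (adjusted p of 0.0533 by edgeR). That of chrd was lost without head osteoblast 2 or trunk osteoblast 3 and with the replicate block (up to 0.0538).

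Among 60 of the 200 possible regroupings of the libraries, 2 reached the count of 74 interaction genes, the real grouping included. The other, at 806 genes, swapped head and trunk within a single cell type, and the next gave 65. Apart from that swap, the other regroupings mix head and trunk libraries within a group. Differences between body parts then widen the spread inside groups and lower the count. These counts therefore cannot decide whether the interaction is real. For each of the 4 pairwise comparisons only 1 of 10 splits, the real one, reached the count, and the others gave 0. With 10 splits the share cannot fall under 0.05. The other splits also mix the groups compared, so any real difference widens the spread within them.

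Ribosomal protein genes were picked by symbol, which also took in rps19bp1, a gene of a binding protein. Of 85 such genes 11 held under 100 counts over the 12 libraries, against a median of 128231 for the other 74. rpl32 held 0 and rpl9 held 2. Among the 10 nearest genes of each, 75.5% were short of counts, against 43.3% for the others. The permutation p was 1e-05, the smallest that 100000 resamples allow. A candidate explanation is that reads were lost over whole stretches of the assembly, which may also apply to col1a1a and col2a1a. For 0% of the 11 genes did 50% or more of the exon bases lie inside exons of another annotated gene. The share was 48.7% for rpl9. Duplicated sequence was not tested for lack of a genome sequence. Of 32020 genes with a chromosome, 6330 held no count in any library. They included the list gene shha, and the bone gene bglap held 9 counts, so both went untested. Whether such genes were unexpressed or lost their reads was not tested.

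Photoreceptor and lens transcripts were higher in head than in trunk osteoblasts. With each head osteoblast library left out in turn, at least 8 of the tested members were past the threshold, so a single library does not account for the pattern. In 7 of 12 members every head chondrocyte library also lay above every trunk chondrocyte library, which is consistent with RNA from eye cells in the head sorts. Expression of these genes by the osteoblasts themselves, or an incomplete GFP and mCherry gate, was not tested.

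Skeletal muscle transcripts were lower in head than in trunk chondrocytes. With each trunk chondrocyte library left out in turn, at least 15 of 18 tested members were past the threshold. Levels of the muscle genes in trunk chondrocyte 3 followed their mean in the other 5 trunk libraries with a Spearman correlation of 0.961 across members. RNA from muscle cells and expression by the sorted cells would both give such ranks, and the genes differ widely in level in every library, so the source stays open.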

How the results depend on the processing

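The alternatives of leaving out a pair of libraries and of sample quality weights were chosen after the result was seen, and the other tests were chosen before.

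In head against trunk osteoblasts 352 genes became 158 at an adjusted p under 0.01, 231 with the replicate block, 815 with DESeq2, 990 without head osteoblast 1 and trunk chondrocyte 3, and 1535 with limma weights. Leaving out single libraries gave 146 to 475. In head osteoblasts against chondrocytes 2505 became 1035 at 0.01, 5311 without the pair and 5479 with weights, and single libraries gave 1220 to 3393. In the trunk 2593 became 1129 at 0.01, 4334 without the pair and 5311 with weights, and single libraries gave 1297 to 4379.

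In head against trunk chondrocytes 517 became 108 at 0.01, 227 with the block, 1172 with DESeq2, 1440 without the pair and 1140 with weights, and single libraries gave 119 to 1221. The 74 interaction genes became 14 at 0.01, 246 without a filter, 26 with the block, 532 with DESeq2, 358 without the pair and 380 with weights, and single libraries gave 21 to 158. Deviations of log2 CPM from the group mean were correlated between libraries of different groups. Same-numbered pairs had a median of −0.005 (0.016 for other pairs), with 3 of 18 over 0.1 and a highest of 0.195. Whether the numbers stand for shared sorts is not known.

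The correlation of the head and trunk cell type differences, 0.499, became 0.668 over called genes, 0.316 without a filter and 0.642 without the pair. The list skeletal muscle in trunk osteoblasts against chondrocytes turned sign at an adjusted p of 0.979 without trunk chondrocyte 3, against 3.33e-06 without trunk chondrocyte 2. The list dissociation stress in head against trunk chondrocytes turned sign at 0.969 without trunk chondrocyte 2, against 9.03e-07 without trunk chondrocyte 3. No named gene turned sign past the threshold.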

Other observations

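The gene families of this part were tested after the data were seen. The tests covered 165 families of at least 10 tested genes sharing a symbol stem, 1320 tests in all, by the hypergeometric distribution with Benjamini-Hochberg adjustment, and 30 passed. This test takes the genes of a family as independent of each other. Correlation within families was not allowed for, so the adjusted p of this part can be too small.

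Collagen genes (col) were higher in osteoblasts in 25 of 48 cases in the head (4.43 expected, adjusted p = 1.85e-11 by edgeR calls and the hypergeometric test) and in 22 of 48 in the trunk (3.78 expected). Cartilage members such as col2a1b, col9a1a and col9a2 were lower in both body parts. Genes with the symbol stem sec, which include vesicle coat, translocon and lipid-binding genes, were lower in 14 of 22 cases in the head (1.61 expected) and 13 of 22 in the trunk (2.03 expected). In trunk osteoblasts atp genes were lower in 28 of 74 cases (6.83 expected) and cox genes in 13 of 24 (2.22 expected), a direction that library totals shift upward by 0.51 in the median. That comparison includes trunk chondrocyte 3, with 10.85% of its counts in the skeletal muscle list, and the families were not tested without it. bmp genes were higher in trunk osteoblasts than chondrocytes in 7 of 11 cases (0.87 expected). Genes of the her family of transcription factors were higher in head osteoblasts than chondrocytes in 6 of 10 cases (0.92 expected, adjusted p = 0.00532 by edgeR calls and the hypergeometric test), all of them her4 and her15 genes. Neuronal and glial markers rose in 14 of 19 cases in the same comparison.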
